A study of Arabidopsis thaliana with 6 samples.

How the data were processed

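Total RNA of whole young Arabidopsis thaliana seedlings (cotyledons, hypocotyl and primary root) was labelled with biotin and hybridised to ATH1 expression arrays, 1 array per sample. The 6 samples fall into 3 groups of 2: wild type Col-0 grown with 5 µM norflurazon, wild type Col-0 without it, and the gun1,gun5 double mutant with 5 µM norflurazon. Groups and replicate numbers were taken from the sample labels. The labels do not say whether the samples of a group came from separate plates or plantings, so p-values measure the spread between these samples, which may in part be technical.

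The deposited values are array intensity values on a linear scale, computed with MAS5 per the submitters' processing notes; its version is not given in the sources used here. Each array's mean after leaving out signals below the 2nd and above the 98th percentile lay between 99.96 and 99.97, so the arrays had been scaled to 100 before deposit. No detection calls were used here, so a signal near 0 is known only as dim. Of the values, 98 were 0 and none of these belonged to a probe set that was tested. The table of the 6 arrays held 22810 probe sets, of which 64 were control probe sets and were left out of the tests. The number of arrays limits the precision of every value.

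Intensities were transformed to log2(signal + 0.05), the pseudocount being 0.5 times the smallest positive signal, 0.1. Probe sets were kept when their mean log2 signal over the 6 arrays was at or above the 40th percentile of the non-control probe sets, a signal of 27.6, which left 13648. The scaling of the deposited table was kept. A linear model with 1 mean per group was fitted over all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), which left 3 residual degrees of freedom and 4.89 prior degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All adjusted p-values of single genes are two-sided and come from this limma model. Every log2 change is a difference of group means on this scale and depends on the pseudocount for dim genes.

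Probe sets were named from the platform annotation given with the series, updated through the RefSeq gene table of assembly TAIR10.1. Of all probe sets, 13513 named 1 gene, 503 named several and 8794 are unnamed here; 13459 of those with 1 gene were matched to a locus. Among the tested probe sets, 7315 named 1 gene, 276 several and 6057 are unnamed here. Of the 424 loci in the 26 gene lists written by hand, 75 were named and 64 of these passed the filter; the lists of the plastid and mitochondrial genomes had 62 and 12 tested loci. GUN1 and GUN5 were not among the named loci, and their own signals are not analysed here. The same holds for GUN4, HO1, HY2, GLK1, GLK2, LHCB1.4, LHCB2.3 and RBCS1A.

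Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, on 1 probe set per locus (the one with the highest mean signal, 7256 loci), for lists with at least 5 measured loci; fry was run beside it. Of 28 lists fixed before the data were examined, 5 reached that size and 7 had no measured member. A further 16 lists were added after the annotation had been read and before any change between groups was computed; they were adjusted separately. The genes named in the text follow a rule fixed at the same time as those 28 lists. Per comparison it takes the 8 largest rises and the 8 largest falls among probe sets past the threshold that name 1 locus and whose arrays do not overlap between the groups. It adds, for each list, the 2 members with the largest change past the threshold, or the member with the smallest p where none passed. Other genes of a list are named as its members.

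The overlap of 2 comparisons that share the wild type norflurazon arrays was set beside 100 simulations of unchanged groups and beside the count that independent lists would share. The difference between mutant and wild type on norflurazon was also computed as a share of the loss in the wild type. Probe sets were chosen on one replicate number and measured on the other, so that the noise of the measured arrays did not enter the choice. The loss and the difference used the same wild type norflurazon array, whose noise enters both. The first 2 comparisons, camera and the share were tested on simulated arrays with the pooled spread of the real ones. With 13648 probe sets, 50 of 100 probe sets changed 2-fold and 96 of 100 changed 4-fold were recovered for norflurazon against control, with 15 false calls among 13418 unchanged probe sets. For the mutant against the wild type, 6 of 50 probe sets changed 2-fold were recovered. Camera called the shifted simulated list and 0 of 20 unchanged ones, and a share of 50% put in was estimated as 50.3%. The simulated probe sets varied independently of each other and with the same spread in each group. Camera was therefore not tested where genes of a list vary together.

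The alternatives tried were 2 other scalings of the arrays, no filter and a filter at the 60th percentile, a pseudocount of 16, 2 other variance models, a fit of only the 4 arrays compared, a block for the replicate number and leaving out each array in turn. For the lists an estimated correlation and fry were tried, and for the share of the loss other fold limits and the median. The estimated correlation rests on 3 residual degrees of freedom, so a list that did not pass with it is not shown unchanged. A fit without both norflurazon arrays numbered 1 was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9. With 2 arrays per group neither a test for outlying samples nor a count over other splits of the samples applies.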

Results

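Transcript levels were measured on 6 ATH1 arrays, 2 for each of 3 groups of seedlings. All seedlings were grown for 3 days in darkness and then for 3 days in continuous white light at 23 °C on medium with 1.5% (w/v) sucrose. Norflurazon is a herbicide that blocks carotenoid synthesis, so that chloroplasts are bleached in the light, and it was present at 5 µM in the medium of 2 groups. One of these was wild type Col-0 and the other was the gun1,gun5 double mutant; gun (genomes uncoupled) mutants were isolated because nuclear photosynthesis genes stay expressed in them when plastids are damaged. Wild type seedlings without the herbicide were the control. An untreated mutant group was not analysed here, so a difference between mutant and wild type on norflurazon is not a test of how the mutation changes the response to it.

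The 2 control arrays were the most alike, with a standard deviation of 0.271 for their log2 difference over 13648 probe sets, against 0.451 for the mutant pair and 0.589 for the wild type norflurazon pair. No 2 arrays held the same values: the largest number of equal signals between any pair was 273. The ratio of 3′ to 5′ signal of the actin control probe sets, a sign of RNA quality, ran from 1.65 on wild type norflurazon replicate 1 to 3.63 on wild type norflurazon replicate 2, and was 2.46 and 2.78 on the control arrays and 2.00 and 3.21 on the mutant arrays. For GAPDH the ratio lay between 0.952 and 1.21, and for ubiquitin it was at most 1.96. The control probe set for 25S ribosomal RNA had signals of 2511.1 and 8.2 on wild type norflurazon replicates 1 and 2. RNA without poly(A) tails may therefore have been labelled to different extents. How far plastid and mitochondrial signals follow transcript levels was not tested, and this limit holds for every result on these genomes.

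The first comparison asked how norflurazon changed the wild type transcriptome. Genes of the photosynthetic apparatus fell together. Of 78 listed nuclear genes for antenna proteins, photosystem subunits, electron transport with the ATP synthase, and the Calvin cycle, 12 were measured. All 12 fell, with a median log2 change of -2.20. Electron transport and the ATP synthase were represented by 1 gene. The antenna protein gene LHCB4.2 (AT3G08940) went from a signal of 2423 ± 245 (SD, n = 2) in the control to 140.4 ± 84.9 (SD, n = 2) on norflurazon, a log2 change of -4.25 ± 0.39 (SE; adjusted p = 0.000444). PORB, the protochlorophyllide reductase of chlorophyll synthesis, fell by 3.70 on the log2 scale, and 50 of the 62 measured transcripts of the plastid genome fell (adjusted p = 0.159 for the list with an estimated correlation).

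In total 1236 probe sets rose and 1345 fell in the wild type on norflurazon, 18.9% of those tested; 523 of the rises and 882 of the falls were at least 2-fold. PSAE-1, a subunit of photosystem I, fell by 3.73 (adjusted p = 0.000401) and PSAN, another, by 2.27 (adjusted p = 0.000289). The Calvin cycle enzymes SBPASE and PRK fell by 2.91 and 2.80. The ATP synthase subunit gene ATPC1 fell by 1.85. The pooled list of these nuclear genes passed camera (adjusted p = 1.12e-15, and adjusted p = 0.125 with an estimated correlation), and all 12 passed when adjusted over the list alone. Of 27 measured genes for photosystem assembly and the NDH complex 20 fell, among them NdhL from 823.4 ± 60.7 to 74.7 ± 5.66 (SD, n = 2) and AT1G51400, which encodes a small photosystem II protein, at a log2 change of -2.96. The median of that list was -1.22 (adjusted p = 2.31e-16, and adjusted p = 0.0879 with an estimated correlation). In photorespiration, 3 of 4 measured genes fell, including the glycine decarboxylase subunit gene AT1G32470 by 2.80 and the hydroxypyruvate reductase gene HPR by 2.19.

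Among 9 measured genes of tetrapyrrole synthesis, the pathway to chlorophyll and haem, 5 fell, and 6 when adjusted over the list alone. PORB went from 786.0 ± 34.4 to 61.05 ± 13.1 (SD, n = 2), and CHLI2, a subunit of magnesium chelatase, fell by 1.56 (adjusted p = 0.00205). The list median was -0.91 (adjusted p = 2.74e-05, and adjusted p = 0.182 with an estimated correlation). Of 7 nuclear genes for plastid ribosomal proteins 6 fell, with AT1G29070 lowest at -1.03 and AT3G13120 at -0.98, and the list had an adjusted p of 2.74e-05, and an adjusted p of 0.182 with an estimated correlation. The plastid-encoded transcripts had a median change of -1.50 (adjusted p = 1.62e-31, and adjusted p = 0.159 with an estimated correlation), and 60 of 62 passed when adjusted over the list alone. The NDH subunit transcript ndhA was at -3.19, the ATP synthase transcript atpF at -2.96 and the photosystem I core transcript psaA at -2.93. Signals of atpF were 200.1 and 58.4 on the norflurazon arrays and those of psaA 118.5 and 24.5, and without wild type norflurazon replicate 2 psaA was at -1.80. For plastid-encoded polymerase and ribosomal subunits 12 of 18 fell, including rps2 by 2.01 and rps4 by 1.89.

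Rises were found in other groups. Of 83 measured genes for cytosolic ribosomal proteins 37 rose and 0 fell, and 56 rose when adjusted over the list alone; the median was 0.50 (adjusted p = 2.29e-14, and adjusted p = 0.125 with an estimated correlation). AT4G39200 rose by 1.66 and AT1G15250 by 1.44, which was 0.92 and did not pass without control replicate 1. The 3 reference genes had a median of 0.41, with 1 past the threshold. Of 15 nuclear genes for mitochondrial respiration 4 rose (adjusted p = 0.0367 for the list, and adjusted p = 0.188 with an estimated correlation), among them the cytochrome c genes CYTC-2, from 151.6 ± 2.76 to 774.0 ± 77.6 (SD, n = 2), and CYTC-1, by 1.08. The transcripts of the mitochondrial genome had a median of 0.64 (adjusted p = 0.0193, and adjusted p = 0.463 with an estimated correlation), with 1 of 12, nad4, past the threshold at 1.14; by fry its adjusted p was 0.27. Its median over the controls was 0.92 on wild type norflurazon replicate 1, where the control probe set for 25S ribosomal RNA had a signal of 2511.1, and 0.33 on replicate 2, where it had 8.2. This last list did not pass without wild type norflurazon replicate 1 (median 0.33, adjusted p = 0.472) or with a filter at the 60th percentile (adjusted p = 0.0518), and the respiration list did not pass without wild type norflurazon replicate 2 (adjusted p = 0.0633).

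Among probe sets that named 1 locus and had arrays that did not overlap between the groups, AT2G41730 rose from 4.25 ± 3.04 to 194.6 ± 72.5 (SD, n = 2), a log2 change of 5.66 ± 0.49 (SE). Its control signal was near 0, and with a pseudocount of 16 the change was 3.34, below AT5G51440 at 3.54, ICL at 3.53 and AT2G04050 at 3.44. AT2G19970 rose by 4.46, which was 3.06 with a pseudocount of 16, and AT2G04050, a transporter gene of the MATE family, by 4.23. AT5G51440, a small heat shock protein gene, rose by 3.96 with signals that differed widely between the norflurazon arrays (958.6 ± 993, SD, n = 2). ICL, the isocitrate lyase of the glyoxylate cycle, rose from 145.5 ± 11.7 to 1850 ± 254 (SD, n = 2). AT2G21640, known to respond to oxidative stress, rose by 3.56. The other rises named by the rule were AT1G47570 at 3.43, which was 1.74 with a pseudocount of 16, and the chaperone gene Fes1A at 3.14, also with unequal signals on the norflurazon arrays (1038 ± 964, SD, n = 2). Without wild type norflurazon replicate 1 AT5G51440 was at 2.61 and Fes1A at 2.00, and without control replicate 1 AT1G47570 was at 1.76 and did not pass. Of 4 antioxidant enzyme genes 2 rose and 2 fell. The copper chaperone of superoxide dismutase, CCS, rose by 2.37 and the stromal ascorbate peroxidase SAPX by 0.86, while the thylakoid ascorbate peroxidase TAPX fell by 2.60. Among the falls AT3G28270 was at -8.25, from 375.6 ± 144 to 1.15 ± 0.212 (SD, n = 2); it was -4.46 with a pseudocount of 16. AT1G21500 was at -4.60, AT3G62550 at -4.01, AT5G38980 at -3.96, AT2G25510 at -3.95 and AT5G48490 at -3.83. The sucrose phosphate synthase gene ATSPS4F fell from 247.8 ± 23.1 to 16.2 ± 7.07 (SD, n = 2).

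Smaller changes were seen in several other lists. The light signalling gene HYH rose by 0.92, and the sugar transporter gene SWEET17 rose from 224.6 ± 22.8 to 491.7 ± 150 (SD, n = 2), with SWEET2 at 0.75. Of 3 starch enzyme genes SBE2.2 and DPE1 fell, at -1.12 and -1.25. COR15B, a cold-regulated chloroplast protein gene, fell by 1.84 and the dehydration gene DI21 rose by 1.27. AT4G34270, placed in the list of reference genes, was higher by 0.79 (adjusted p = 0.0459). The clock gene GI had a log2 change of 0.02 (adjusted p = 0.973). Of the 5 heat shock genes 0 passed the limma test, and 0 had an unadjusted p under 0.05, although their median change was 3.54. Their signals on wild type norflurazon replicate 1 lay between 818.5 and 2739, and on replicate 2 between 14.1 and 83.2.

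**Figure D1:**
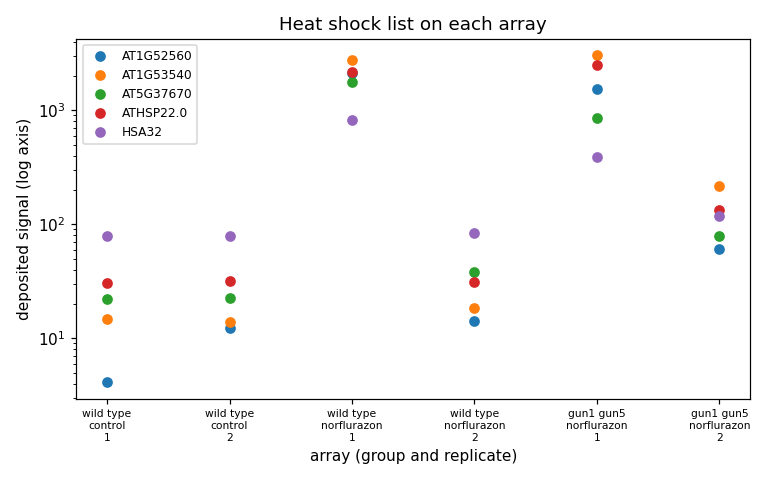
Deposited signal (log axis) of the 5 measured heat shock genes on each of the 6 arrays, 1 point per gene. The signals lie between 818.5 and 2739 on wild type norflurazon replicate 1 and between 14.1 and 83.2 on replicate 2, and the mutant array numbered 1 is also above the mutant array numbered 2.

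With a correlation estimated from these arrays, on 3 residual degrees of freedom, none of the 5 fixed and 16 added lists passed camera in this comparison. The count of 2581 changed probe sets was 603 without control replicate 1, 677 without control replicate 2, and 5133 without both norflurazon arrays numbered 1, where the spread comes from the control pair alone.

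**Figure D2:**
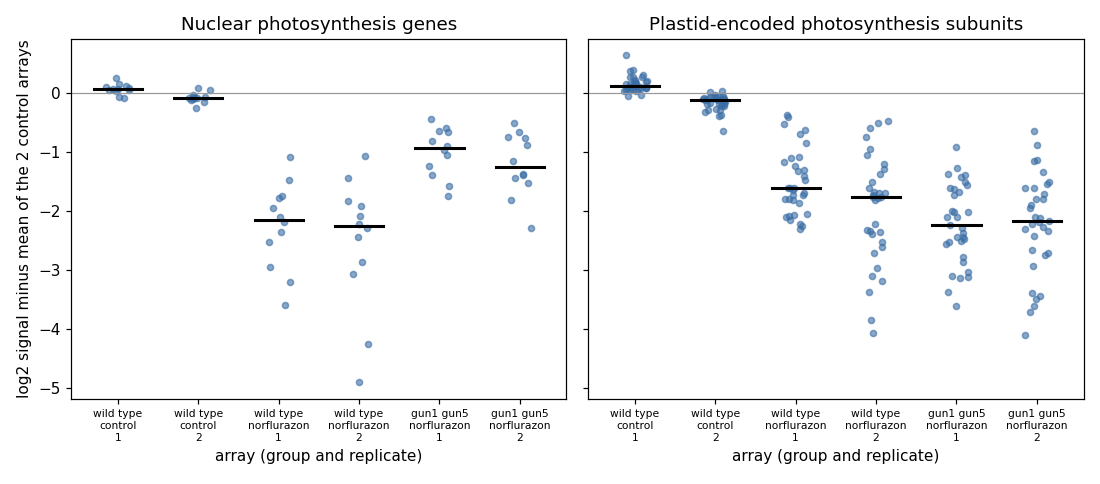
Log2 signal of each measured gene minus the mean of the 2 control arrays, for 12 nuclear photosynthesis genes (left) and 33 plastid-encoded photosynthesis subunits (right) on each of the 6 arrays. Points are genes and bars are medians. The nuclear medians were -2.15 and -2.25 on the wild type norflurazon arrays and -0.93 and -1.26 on the mutant arrays. Signals of plastid-encoded transcripts were not higher in the mutant.

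The second comparison asked how gun1 gun5 differed from the wild type when both were grown on norflurazon. Nuclear photosynthesis genes were higher in the mutant: 10 of 12 rose, with a median log2 difference of 1.23. LHCB4.2 had a signal of 608.6 ± 162 (SD, n = 2) in the mutant and 140.4 ± 84.9 (SD, n = 2) in the wild type, a difference of 2.23 ± 0.39 (SE; adjusted p = 0.0268). Signals of plastid genome transcripts did not follow, within the limit on labelling given above. Their median difference was -0.46, with 0 of 62 higher and 2 lower.

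In all 250 probe sets were higher and 152 lower in the mutant, 2.95% of those tested. The spread behind these calls was pooled over 3 groups. It included the control pair, which is not compared here and varied least (standard deviation 0.271, against 0.451 and 0.589). The p-values of this comparison may therefore be too small. Deviations of same-numbered arrays correlated at 0.451 between its 2 groups. The fit left this out, which may act the other way. The pooled nuclear list passed camera (adjusted p = 1.24e-18, and adjusted p = 0.0962 with an estimated correlation), and all 12 genes passed when adjusted over the list alone. PSAE-1 was higher by 2.49, the photosystem II subunit gene PSBY by 1.31, SBPASE by 1.45, PRK by 1.48, LHCB4.1 by 1.22 and ATPC1 by 0.87. The 2 genes that did not pass over all probe sets were LHCB4.3 at 0.59 (adjusted p = 0.162) and PSBW at 0.62 (adjusted p = 0.0966). Of the genes for photosystem assembly and the NDH complex 11 of 27 rose (adjusted p = 2.87e-21 for the list, and adjusted p = 0.058 with an estimated correlation). CaS, a thylakoid protein gene, went from 159.1 ± 6.36 to 527.8 ± 48.6 (SD, n = 2), and AT1G51400 was higher by 1.27. In tetrapyrrole synthesis 2 of 9 rose, PORB by 1.90 and the geranylgeranyl reductase gene AT1G74470 by 1.07, and 4 when adjusted over the list alone. The list passed at an adjusted p of 2.82e-07, with an adjusted p of 0.187 with an estimated correlation. Of the plastid ribosomal protein genes 2 of 7 rose, AT1G29070 by 0.85 and AT3G54210 by 0.71, and 5 when adjusted over the list alone (adjusted p = 5.39e-07 for the list, and adjusted p = 0.187 with an estimated correlation). HPR was higher by 1.23.

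The plastid genome list passed camera in the opposite direction (adjusted p = 1.9e-11, and adjusted p = 0.187 with an estimated correlation) and did not pass by fry (adjusted p = 0.0708), with 20 of 62 transcripts at an unadjusted p under 0.05 and 4 lower when adjusted over the list alone. Its 2 members past the threshold were ndhJ, at 315.3 ± 37.6 in the wild type and 156.3 ± 11.6 in the mutant (SD, n = 2), and rps16, lower by a log2 difference of -0.95. The Rubisco large subunit transcript rbcL was at -0.99 (adjusted p = 0.0657). The difference between the 2 compartments was tested within the union of 12 nuclear and 33 plastid-encoded photosynthesis genes. The nuclear members ranged from 0.59 to 2.49 and the plastid-encoded ones from -1.24 to 0.01. Camera gave p = 7.09e-24 with the preset correlation and p = 0.000879 with an estimated correlation. It allows for correlation only among the 12 nuclear genes and treats the 33 plastid-encoded ones as independent. Both p-values may therefore be too small. Neither allows for labelling that differs between nuclear and plastid transcripts, which was not tested. Transcripts of the mitochondrial genome had a median of 0.65 (adjusted p = 0.000331, and adjusted p = 0.299 with an estimated correlation), with 0 of 12 past the limma threshold and 5 at an unadjusted p under 0.05. The list did not pass without wild type norflurazon replicate 2 (median 0.48, adjusted p = 0.0744) or without mutant replicate 1 (median 0.20, adjusted p = 0.171). The 33 plastid-encoded photosynthesis subunits, with 0 past the limma threshold, 0 when adjusted over the list alone and 7 at an unadjusted p under 0.05, passed camera as a list (adjusted p = 8.39e-06, and adjusted p = 0.371 with an estimated correlation). They did not pass by fry (adjusted p = 0.187) or without both norflurazon arrays numbered 1 (adjusted p = 0.0523). By fry the mitochondrial list had an adjusted p of 0.298.

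Other genes set the mutant apart. AT3G28270, with 1.15 ± 0.212 (SD, n = 2) in the wild type, was higher by 5.74; with a pseudocount of 16 this was 2.22, below PSAE-1 at 2.40. AT1G21500 was higher by 2.56, AT2G35260 by 2.51, AT5G42760 by 2.42, AT4G28080 by 2.13 and AT5G38980 by 2.13. COR15B was at 107.5 ± 10.2 in the mutant and 25.3 ± 8.2 in the wild type (SD, n = 2). The ubiquitin ligase gene PUB19 was higher by 1.38. Among the falls, AT5G02890 was at -3.77 and AT5G50335 at -3.21; with a pseudocount of 16 these were -2.03 and -1.71. AT2G43620, a gene of the chitinase family, was lower by a log2 difference of -3.13. AT4G12490 and AT4G12500, neighbouring genes for proteins of the lipid transfer family, were at -2.40 and -2.29. AT5G45670 was at -2.29, DRT100 at -2.22 and AT1G65500 at -2.13. The expansin gene EXPA8, whose product loosens cell walls, went from 373.0 ± 104 to 84.5 ± 9.76 (SD, n = 2), and the list of expansins and xyloglucan endotransglucosylases had a median of -0.48 with 1 of 15 lower, 4 when adjusted over the list alone (adjusted p = 0.00248, and adjusted p = 0.344 with an estimated correlation). That list did not pass without wild type norflurazon replicate 1 (adjusted p = 0.0535) or without mutant replicate 2 (adjusted p = 0.13), nor by fry (adjusted p = 0.178). Among UDP-glycosyltransferase genes UGT87A2 was higher by 1.39 and UGT72E1 lower at -1.37. For cytosolic ribosomal proteins 0 of 83 passed the limma threshold and 1 had an unadjusted p under 0.05, with a median of 0.01.

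No list of this comparison passed camera with an estimated correlation. The count of 402 was 118 and 117 without control replicate 1 or 2, 175 and 81 without mutant replicate 1 or 2, 775 without wild type norflurazon replicate 2, 1600 without both norflurazon arrays numbered 1, and 109 when only the 4 arrays compared were fitted.

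The third comparison set the treated mutant against the untreated wild type, so genotype and treatment both differed. Nuclear photosynthesis genes were still below the control level: 10 of 12 were lower, with a median of -1.07 (adjusted p = 1.87e-08, and adjusted p = 0.0893 with an estimated correlation). The plastid genome was lower throughout, with 61 of 62 transcripts past the threshold and a median of -1.94 (adjusted p = 1.72e-40, and adjusted p = 0.113 with an estimated correlation). Genes for cytosolic ribosomal proteins were higher, 41 of 83 (adjusted p = 1.53e-16, and adjusted p = 0.0893 with an estimated correlation).

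Here 1167 probe sets were higher and 1404 lower. LHCB4.2 remained lower at -2.02 and LHCB4.3 at -1.70, PSAE-1 at -1.24, SBPASE at -1.45 and PRK at -1.32. The Calvin cycle genes RCA and AT1G56190 were at -0.48 and -0.77 and did not pass (adjusted p = 0.0621 and 0.0534). In tetrapyrrole synthesis 3 of 9 were lower, PORB at -1.80 and CHLI2 at -0.92 among them, and the list did not pass (adjusted p = 0.0735). Plastid ribosomal protein genes had a median of -0.24, with 0 of 7 past the limma threshold and 1 at an unadjusted p under 0.05 (adjusted p = 0.13 for the list). Of the genes for photosystem assembly and the NDH complex 13 of 27 were lower and 1 higher, with NdhL at -2.45 (adjusted p = 5.39e-06 for the list, and adjusted p = 0.0893 with an estimated correlation). Plastid-encoded ndhA was at -3.63, atpF at -3.57, psaA at -3.54 and ndhE at -2.82. The falls named by the rule outside the plastid were those of AT5G50335 at -5.07, which was -3.31 with a pseudocount of 16, ECS1 from 1727 ± 139 to 61.6 ± 10.6 (SD, n = 2), AT5G44580 at -4.61, AT4G33550 at -4.19 and AT1G73120 at -3.76.

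Among the rises were AT2G41730 at 6.16, ICL at 4.04, AT2G04050 at 3.99, AT2G19970 at 3.49, AT5G51440 at 3.42, Fes1A at 3.26, AT1G47570 at 3.19 and AT5G53770 at 3.13. With a pseudocount of 16 AT2G41730 was at 3.81, AT2G19970 at 2.19, AT1G47570 at 1.56 and AT5G53770 at 1.74. Without control replicate 1 or 2 AT1G47570 was at 1.52 and 4.86. ICL had signals of 1281 and 4466 on the mutant arrays. CYTC-2 was higher by 2.46, the succinate dehydrogenase gene SDH2-1 by 1.37 and CCS by 2.73. Of the mitochondrial genome 6 of 12 transcripts were higher (median 1.37, adjusted p = 2.37e-05, adjusted p = 0.432 with an estimated correlation, and adjusted p = 0.091 by fry). Among them nad6 was at 2.93, with 316.2 ± 276 (SD, n = 2) on the mutant arrays and 1.89 without mutant replicate 1, where it did not pass, and nad5 at 2.28; a second probe set of nad5 gave 3.30. The list median over the controls was 1.70 on mutant replicate 1, an array that also had high heat shock and 25S ribosomal RNA signals, and 0.88 on replicate 2; on the wild type norflurazon arrays it was 0.92 and 0.33. Without mutant replicate 1 the list passed (adjusted p = 0.000875) with 1 of 12 transcripts past the threshold, and without control replicate 1 or 2 there were 1 and 0. Of 15 expansin and xyloglucan endotransglucosylase genes 4 were lower, EXPA8 at -2.39 and XTH19 at -2.27 (adjusted p = 0.00165, adjusted p = 0.205 with an estimated correlation, and adjusted p = 0.0567 by fry); XTH19 was at -1.34 without mutant replicate 2. In the list of stress-responsive CML, PUB and WRKY genes 5 of 12 were lower, including the ERF gene ORA47 at -2.24 and WRKY22 at -1.76 (adjusted p = 0.0106, and adjusted p = 0.125 with an estimated correlation); the list did not pass without mutant replicate 1 (adjusted p = 0.0694). The heat shock list passed camera (adjusted p = 0.0442, and adjusted p = 0.481 with an estimated correlation) with 0 of 5 genes past the limma threshold and 2 at an unadjusted p under 0.05; fry gave an adjusted p of 0.267. Its median over the controls was 6.32 on mutant replicate 1 and 2.08 on mutant replicate 2. The list did not pass without mutant replicate 1 (adjusted p = 0.204), after quantile normalisation (adjusted p = 0.0569), with a filter at the 60th percentile (adjusted p = 0.0745) or with a pseudocount of 16 (adjusted p = 0.067).

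The camera calls of this comparison were also lost with an estimated correlation. The count of 2571 was 3968 with only the 4 arrays compared, and it moved in both directions when single arrays were left out.

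The first 2 comparisons were then set against each other to ask how far the differences between mutant and wild type on norflurazon fell on probe sets that norflurazon had changed in the wild type. Of the 250 probe sets higher in gun1 gun5 than in the wild type on norflurazon, 231 had been lowered by norflurazon in the wild type, 92.4% of them and 17.2% of the 1345 lowered probe sets. LHCB4.2, PSAE-1, PORB, CaS, SBPASE and PRK were in this set. In the other direction, 17 probe sets raised by norflurazon were lower in the mutant, 11.2% of the 152. A further 21 probe sets were lowered by norflurazon and lower in the mutant, and 1 was raised and higher in the mutant.

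**Figure D3:**
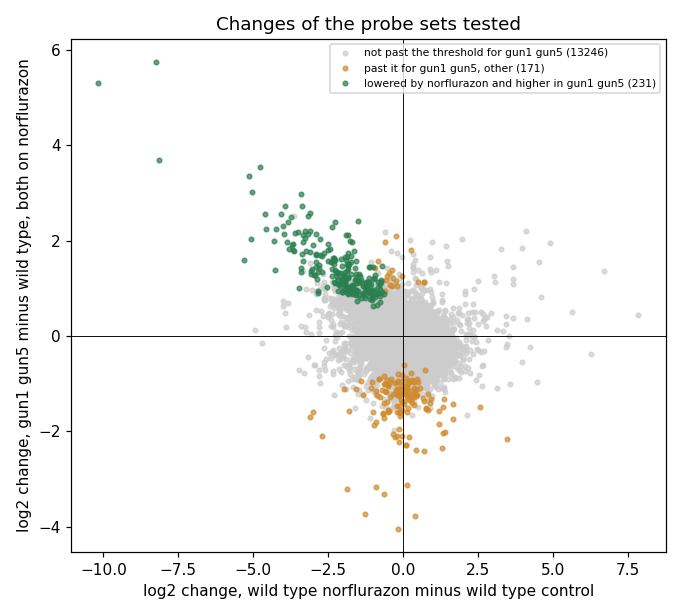
Log2 change on norflurazon in the wild type (horizontal) against the log2 difference between gun1 gun5 and the wild type on norflurazon (vertical), 1 point per probe set tested. The 231 green points were lowered by norflurazon and higher in the mutant, and orange points passed the threshold for the mutant in another way.

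Both comparisons use the 2 wild type norflurazon arrays with opposite sign, so chance alone gives some overlap. In 100 simulations of unchanged groups that shared these arrays the first overlap averaged 0.12 and was at most 2. Hardly any probe set is called in such groups, so this gives chance with no effect, and not what the sharing adds where norflurazon has effects. Independent lists of these sizes would share 24.6. For the second overlap the simulations gave at most 1 and independent lists would share 13.8. Over all probe sets the covariance of the 2 sets of log2 changes was -0.1199, against a simulated mean of -0.0361. The simulations gave every group the same spread. The wild type norflurazon pair, shared by both comparisons, differed most (standard deviation 0.589, against 0.271 for the control pair). The simulated covariance therefore understates what the sharing adds, and the gap is not read as an effect. The correlation was -0.347, and the simulated mean was -0.498. Signs were opposite for 59.91% of probe sets, and the simulated mean was 66.62%. In unchanged groups both values follow from the sharing of the arrays alone, and effects of norflurazon move them. They therefore cannot tell whether the 2 sets of changes are related more or less than by the sharing. The 2 shared arrays could not be divided into sets of at least 2. Part of the overlap beyond that of independent lists may come from the sharing. The overlap of 231 was 77 without either control array, 69 and 59 without mutant replicate 1 or 2, and 566 without both norflurazon arrays numbered 1. The overlap of 17 was 32 and 128 without wild type norflurazon replicate 1 or 2, 3 without either control array or without mutant replicate 2, 11 without mutant replicate 1, and 206 without both arrays numbered 1.

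The difference between mutant and wild type on norflurazon was also set against the size of the loss in the wild type, on probe sets at least 2-fold lower on one norflurazon array than on the control array of the same number. For the 1167 chosen on replicate 1, the mean log2 difference was 23.98% of the mean log2 loss on the replicate 2 arrays. For the 1025 chosen on replicate 2 it was 25.36% on the replicate 1 arrays, a mean of 24.67%. These are shares on the log2 scale, and not shares of the lost signal. The level of these probe sets in untreated mutant seedlings is not known here. Among lists that camera found lowered, the ratio of median log2 changes was 55.8% for the pooled nuclear photosynthesis genes. It was 65.8% for photosystem assembly and the NDH complex, 61.6% for tetrapyrrole synthesis and 74.7% for plastid ribosomal proteins. For the plastid genome it was -30.8%. With an estimated correlation these lists did not pass in the wild type, at adjusted p of 0.125, 0.0879, 0.182, 0.182 and 0.159 in this order. These ratios carry no test. They used medians over all arrays without a split of the replicates, so the noise of the shared arrays enters them. In the share of 24.67% the norflurazon array measured also enters both terms, and only the choice of probe sets is kept apart. The ratios of medians are therefore not on the same measure as that share. That share depended on the choice of genes, from 17.93% for those at least 1.5-fold lower to 32.25% for those at least 4-fold lower.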

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

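The test of RNA degradation and the 3 tests of the heat shock signals were chosen only after the result was seen. The control probe set for 25S ribosomal RNA, which the comparisons do not use, had a signal of 2511.1 on wild type norflurazon replicate 1, 115.6 on mutant replicate 1 and 21.0 on mutant replicate 2, all above the control arrays at 15.2 and 11.1. On wild type norflurazon replicate 2 it was 8.2.

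Degraded RNA on wild type norflurazon replicate 1 is argued against, since 0 of 3 ratios of 3′ to 5′ control signal were above all other arrays. RNA without poly(A) tails may have been labelled in that sample: plastid-encoded transcripts differed by a median of 0.12 on the log2 scale between the 2 wild type norflurazon arrays (from -0.67 to 2.27) and mitochondrial ones by 0.47. Neither value decides it, and no biological explanation was tested.

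Heat shock genes were high on both norflurazon arrays numbered 1, with medians of 6.30 and 6.32 over the controls on the log2 scale. An event shared by all 3 arrays numbered 1 is argued against by the controls, which differed by a median of -0.01 (from -1.57 to 0.07). A fault of the wild type array alone is argued against by the mutant arrays, which differed by 3.82 (from 1.74 to 4.65). Norflurazon by itself stays open: the list was at 0.37 over the controls on wild type replicate 2 (from 0.01 to 0.98) but at 2.08 on mutant replicate 2. On that wild type array AT5G51440 and Fes1A, outside the list, had signals of 256.4 and 356.6 against control means of 42.65 and 89.5, and handling of the seedlings numbered 1 stays open too.

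The plastid genome list had a median of -0.46 in the mutant against the wild type on norflurazon, with 2 of 62 transcripts past the threshold and 20 at an unadjusted p under 0.05; it passed camera at the preset correlation but not with an estimated correlation (adjusted p = 0.187) or by fry (adjusted p = 0.0708). The array with the high 25S signal is argued against as the only source of this median, which was -0.33 without that array. Scaling is argued against too, since the medians were -0.45 and -0.43 under 2 other scalings. The largest adjusted p under them was 3.53e-11 by camera. It used the preset correlation, with which the list had passed already, so it adds little. A difference in plastid transcript levels between the genotypes may underlie the pattern and stays a hypothesis. Without an untreated mutant it is not assigned to norflurazon. A difference between the arrays in the labelling of RNA without poly(A) tails was not tested for this pattern and stays open.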

How the results depend on the processing

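The fits without both norflurazon arrays numbered 1 were chosen only after the result was seen. A group left with 1 array is assumed to vary like the others, and without both arrays the spread comes from the control pair alone.

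Without any filter 235 probe sets differed between the mutant and the wild type on norflurazon, and the overlaps were 144 and 10. Without the intensity trend the larger overlap was 151. With only the 4 arrays compared the mutant differed from the treated wild type at 109 and from the control at 3968, with overlaps of 72 and 7. Without both arrays numbered 1 the 3 counts were 5133, 1600 and 5297 and the overlaps 566 and 206. Leaving out 1 array at a time gave 603 to 3110, 81 to 775 and 388 to 4000, with overlaps of 59 to 333 and 3 to 128. In the fits that leave out arrays the pooled spread changes with the pairs left in it. Standard deviations were 0.271 for the control, 0.451 for the mutant and 0.589 for the wild type norflurazon pair. Other causes were not tested.

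Deviations of same-numbered arrays correlated at 0.071 and 0.080 between control and treated groups. Between the treated groups they correlated at 0.451, so their same-numbered arrays deviated together. The numbers were not taken as pairs in any comparison. For the mutant against the treated wild type this leaves the shared deviation in the spread, which may make its p-values too large. With a replicate block the counts were 3195, 591 and 3190 and the smaller overlap 35.

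Of the fixed lists 4, 4 and 3 passed camera; with an estimated correlation 0, 0 and 0 did, and by fry 3, 2 and 1, without the plastid genome in the mutant against the treated wild type and without the mitochondrial genome in each comparison. Of the added lists 7, 6 and 9 passed camera, 0 did in each comparison with an estimated correlation, and 8, 3 and 8 did by fry. The difference between the mutant and the treated wild type, as a share of the loss in the wild type, was taken on the log2 scale. It was 25.80% after quantile normalisation, 25.98% at a common median and 30.96% with a filter at the 60th percentile. With limits of 1.5-fold and 4-fold it was 17.93% and 32.25%, and as a median 27.52%.

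Of 189 results for named genes 155 passed. Of their 2450 values under alternatives 2158 passed in the same direction, 292 did not pass and 0 reversed. The 155 had been picked on the same arrays as large changes past the threshold, so 0 reversals were largely set by that choice. Results that reversed had not passed. Some results that had not passed did so under an alternative, 6 of them with a replicate block. GI on norflurazon was -0.039 after quantile normalisation, -0.02 at a common median and -0.17 to 0.20 without 1 array. In the mutant against the treated wild type, without 1 array, DPE1 ran from -0.011 to 0.29, ICL from -0.52 to 1.28, AT1G53540 from -1.76 to 5.44 and GI from -0.52 to 0.12, and GI was 0.11 without both arrays. Against the control GI ran from -0.51 to 0.13 and was 0.13 without both. Dim genes depend most on the pseudocount.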

Other observations

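The values here come from the planned comparisons, except the count of probe sets high on replicate 1, a test chosen only after the result was seen. In several gene groups few members passed. Of 10 autophagy genes 0 passed the limma threshold in the wild type on norflurazon and 1 had an unadjusted p under 0.05, with ATG8B at 0.70 (adjusted p = 0.0905). Of 6 iron deficiency regulators 0 passed and 1 had an unadjusted p under 0.05, with PYE at -0.72 (adjusted p = 0.0869); in the mutant against the control PYE was lower at -0.98 (adjusted p = 0.0341), and at -0.65 and not past the threshold without mutant replicate 1. Among 4 genes of flavonoid synthesis 0 passed on norflurazon and 2 had an unadjusted p under 0.05, while UGT78D2 was higher in the mutant than in the control by 0.98 (adjusted p = 0.00992).

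Among 9 glutathione S-transferase genes GSTL3 fell at -1.21 and GSTU18 at -1.82 in the wild type. Of 25 UDP-glycosyltransferase genes 2 rose and 2 fell, with UGT85A5 at -1.80 and UGT71C2 at 1.41, which was 0.90 with a pseudocount of 16. The lycopene cyclase gene LYC fell at -0.68 (adjusted p = 0.0247). The zinc finger gene STZ, an oxidative stress marker, was at -1.45 in the mutant against the control (adjusted p = 0.0115). The root markers EXPA18 and EXPA7 did not pass in the comparisons where they were named, with EXPA18 at -0.53 on norflurazon (adjusted p = 0.231) and EXPA7 at 0.76 between mutant and wild type (adjusted p = 0.446).

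On wild type norflurazon replicate 1, 88 probe sets were over 4-fold higher than on replicate 2. For the mutant pair this number was 40, and 35 probe sets were in both sets, against 0.258 if the sets were independent. For the control pair it was 3.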
